A study of Vitis vinifera with 9 samples.

How the data were processed

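Transcripts were profiled by SuperSAGE in 9 libraries of Vitis vinifera (Cabernet Sauvignon): 1 of flowers, 5 of berry skin and 3 of seed. Per the labels' protocols, cDNA primed on the poly(A) tail was cut with NlaIII, whose site is CATG, and EcoP15I released a fragment next to that site. The fragments received adapters with a 4-base index and were amplified by PCR before sequencing. The software that extracted and counted the tags is not given in the sources used here.

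Each deposited file lists tag sequences of 26 bases with 1 score per tag, without a header. Compared with the total tag counts per the labels, the deposited score equalled the tag count in ppm of the library total, rounded to a whole number. Counts were recovered as the score times the label total, scaled back and rounded to the nearest whole number. Scaled and rounded again, they returned the deposited score for 100% of the values in each of the 9 libraries, and these counts were used in the tests. The lowest count listed in any library was 2, so a tag seen once or never is unlisted. A tag names no gene here, because no transcript sequences of the organism were used, and tags are therefore reported by sequence; the gene lists fixed beforehand were not analysed.

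The libraries held between 85312 (seed, 2 weeks) and 342655 (skin, 2 weeks, light) tags by their labels. Those totals served as library sizes, since the listed tags make up part of each library. Sequences with undetermined bases were left out, which kept 33943 of 43227 distinct sequences. Intervals of folds and of shares of counts are 95% exact (Clopper-Pearson) intervals and cover counting error only, since amplified tags without molecular identifiers are not independent molecules.

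There was 1 library per condition, so no difference between 2 libraries has a replicate check, and each test compares the 2 libraries, not the conditions. For each of 9 pairs, every tag with at least 10 counts in both libraries together was tested with a two-sided Fisher's exact test on its count against the rest of the library. Adjusted p-values are Benjamini-Hochberg values over the tags tested in that pair. A tag was called at an adjusted p under 0.05 and a fold of at least 2. A fold against an unlisted tag was computed against a floor of 3 tags in that library and is given as a lower bound.

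Skin and seed were compared over 3 stages (2, 7 and 9 weeks) with limma on log2 of ppm plus a pseudocount of 20, with stage as a block, for tags with a mean of at least 50 ppm. Its residual spread is the variation of the tissue difference between stages, not between replicates. The design written before the data were examined named edgeR for this comparison, but edgeR was not used: limma was chosen for the unit of the deposited files, although the recovered counts would have allowed edgeR to be tried. The recovery of the shade library's calls after light was counted by the sign of the fold, set against 10 simulations of unchanged libraries and against 10 random divisions of the shade counts into a pair of independent parts.

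The tests of the 9 pairs, the thresholds, the naming rule and part of the alternatives were fixed before the data were examined. The rule takes, among called tags with at least 20 counts in both libraries together, the 10 largest folds in each direction. Its parts on gene lists and product names had no gene to act on. The text names the leading tags, and any other tag named was chosen after its values were seen. Because folds followed the GC content of tags, every pair was also tested after centring the log2 folds on the median of tags with the same number of G and C bases (bins of at least 30 tags), with an exact binomial test. That setting, called GC-centred, was added after the data had been seen.

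Further alternatives were the sum of listed tags, TMM and median-of-ratios factors as library sizes, no count minimum, and an exact negative binomial test with an assumed coefficient of variation of 0.2 or 0.4. Others assigned tags with undetermined bases to their match, joined tags on the first 25 bases, left out 1-mismatch neighbours of tags 50 times as frequent, gave unlisted tags 1 count, or left out possible carry-over from late seed.

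The tests were tested on simulated data: libraries with 200 tags changed by known folds. In the pairs of libraries these were drawn from tags well above the count minimum, so recovery of rarer tags was not simulated. Over the 9 simulated pairs, Fisher's exact test with the fold threshold recovered only between 12.9% and 42.1% of 2-fold changes, between 73.0% and 94.1% of 4-fold changes and between 88.6% and 100% of 8-fold changes. A 2-fold change lies at the fold threshold itself, so its recovery is limited by that threshold and not by the exact test alone. Between 2 and 13 unchanged tags were called per pair. A further simulation had a GC trend of 0.3 (log2) per G or C base in every pair and no other change. Fisher's exact test then called between 169 and 644 tags per pair. The GC-centred test called at most 1, since centring removes such a trend by construction. Across the real tags only the slope of shade then light against shade (-0.39) was steeper than 0.3 in size. That of skin against flower, where the simulation gave 644, was 0.058. The skin and seed comparison was simulated with a spread of 0.6 (log2). There limma recovered 59 of 64 tags changed by 2 on the log2 scale. It called 6 unchanged tags of the 2355 tested (17 with a spread of 0.3). In the real values, 48 tags lay at least 4-fold higher in skin and 5 in seed, and 1 of these was called. A real log2 difference of 5.51 was not called (adjusted p 0.0506, limma). The simulated recovery therefore does not give the recovery in the real comparison.

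Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.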

Results

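Tags of 26 bases were counted in 9 libraries from Cabernet Sauvignon vines, 1 library for each tissue, stage and light regime. Flowers gave 276935 tags. Skin of light-exposed berries gave 342655 tags at 2 weeks after flowering, 223284 at 7 weeks and 249251 at 9 weeks. Seed gave 85312, 106290 and 329399 tags at the same stages. At 17 days after flowering, the stage labelled 2 weeks, skin was also taken from clusters kept in light-proof boxes since flowering (shade, 96905 tags) and from clusters boxed for 14 days and then lit for 3 days (shade then light, 104517 tags). Values are in ppm of all tags of the library, and the files do not pair tags with genes. Without replicates, the intervals given with folds are 95% intervals of counting error, and each fold is one between 2 libraries. A fold written as at least a value was taken against the floor for unlisted tags and does not allow for counting error.

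The most frequent tags differed between tissues and stages. CATGTGCCAACCTACGCAGCTACCCT was the most frequent tag in skin at 2 weeks under all 3 light regimes and in seed at 2 weeks, with 49776 ppm in lit skin and 37650 in seed. CATGTGTAAGTATGAACTAATTCAGA led the flower library with 21337 ppm and skin at 7 weeks with 15429. CATGCAAGTTGTCTGGTTCTAGGGCT alone made up 19.97% of seed at 7 weeks, where the 10 most frequent tags held 39.9% of the library, against 9.51% in seed at 2 weeks. CATGGTAGGCTGTACTTTCAAGCTTC led seed at 9 weeks with 43191 ppm. Of 33943 sequences, 1996 were listed in all 9 libraries and 15972 in 1 library only.

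**Figure D1:**
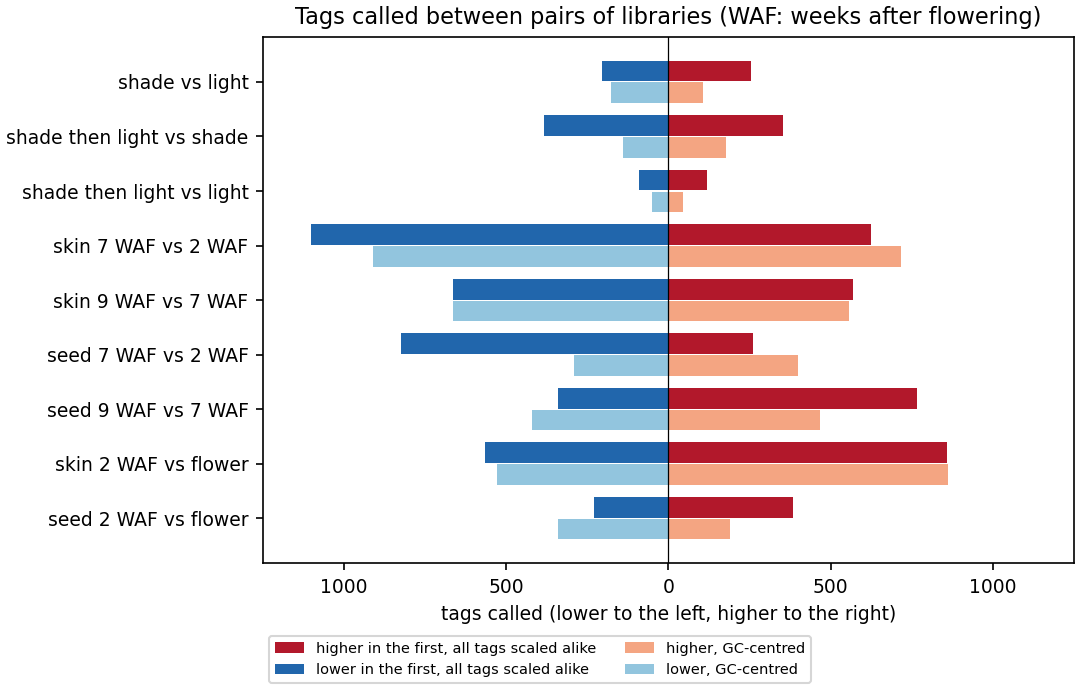
Tags called in each of the 9 pairs of libraries; the horizontal axis gives the number of tags, lower in the first-named library to the left and higher to the right, and the paler bars give the calls after centring on tag GC content. Calls in the shade and light pair went from 459 to 285 with centring, and in the skin pair of 7 and 2 weeks from 1728 to 1628.

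The comparison of shaded with lit skin asked which transcripts depended on light in the young berry. The tag CATGTTGGGTCTGGTTGCACTCGCCT fell from 18651 ppm in light to 784 in shade, a 23.8-fold decrease (19.0 to 30.2). CATGGGTCTACGCCACCAAGTTTGTG fell from 4360 to 196 ppm, a 22.2-fold decrease (14.2 to 37.0). In the other direction, CATGCCGGGGCTGAAATCCGGCGACA rose from 5.84 ppm in light to 557 in shade, 95.5-fold (25.2 to 808), and CATGTGGGGGGCGACAATGTGCTGGT rose from 8.76 to 795, 90.8-fold (29.9 to 450). The tag CATGCCGGGGCTGAAGTCCGGCGACA, which differs from the first of these at 1 base, rose 26.6-fold (18.8 to 38.8), so the counts of the first are uncertain. CATGTTCGGGTTCTTCGTTCAGGCCA, among the commonest tags of lit skin with 8504 ppm, stood at 1063 in shade.

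Of 4722 tags tested with Fisher's exact test, 459 were called, 255 higher and 204 lower in shade. The 4 leading tags had adjusted p-values of 5.46e-31 or less in that exact test. Folds rose with the GC content of the tag (Spearman's rho 0.41 across tags, which are not independent replicates): tags called higher in shade held 60.4% G and C on average and tags called lower 45.2%. With GC-centred folds 285 tags were called, 107 higher and 178 lower, of which 98 and 136 were also among the calls without centring, the 4 leading tags included. Their GC-centred folds were 33.2 and 27.4 for the 2 lower tags and 57.5 and 57.6 for the 2 higher ones. With TMM factors as library sizes the balance turned, with 750 calls, 105 higher and 645 lower. An assumed variation between libraries of 0.2 left 189 calls and of 0.4 left 25, 22 higher and 3 lower.

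Returning shaded clusters to light for 3 days asked which transcripts responded to light again. CATGTAAACGCCACCACTTTTAATAA was unlisted in shade and reached 765 ppm after light, at least 24.7-fold higher, beside 382 ppm in berries kept in light. CATGGCTTCTCTAGCAACCTTAGCTG rose from 20.6 to 507 ppm, 24.6-fold (6.47 to 208). CATGGACGTGGAGAGCGCGTGGAGGT fell from 4943 ppm in shade to 258 after light, a 19.1-fold decrease (12.99 to 29.3). CATGTGTAAGTATGAACTAATTCAGT fell 20.5-fold (6.67 to 102), from 588 to 28.7 ppm; it is a near copy of CATGTGTAAGTATGAACTAATTCAGA, which had 6439 ppm in shade, so its counts are uncertain.

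Of 2751 tags, 739 were called by Fisher's exact test, 354 higher and 385 lower after light, with adjusted p-values of 1.05e-11 or less for these 4 tags in the exact test. The GC trend was steepest in this pair (rho -0.63): the median log2 fold was 1.58 in tags with at most 7 G and C bases and fell to -2.03 in tags with at least 16. GC-centred folds left 318 calls, 178 higher and 140 lower, the 4 tags among them. An assumed variation of 0.2 left 471 calls and of 0.4 left 24. Centring changed the folds of the 4 tags: CATGGACGTGGAGAGCGCGTGGAGGT fell 5.70-fold and CATGTGTAAGTATGAACTAATTCAGT 76.0-fold, while CATGGCTTCTCTAGCAACCTTAGCTG rose 22.4-fold and CATGTAAACGCCACCACTTTTAATAA 10-fold against the same floor.

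**Figure D2:**
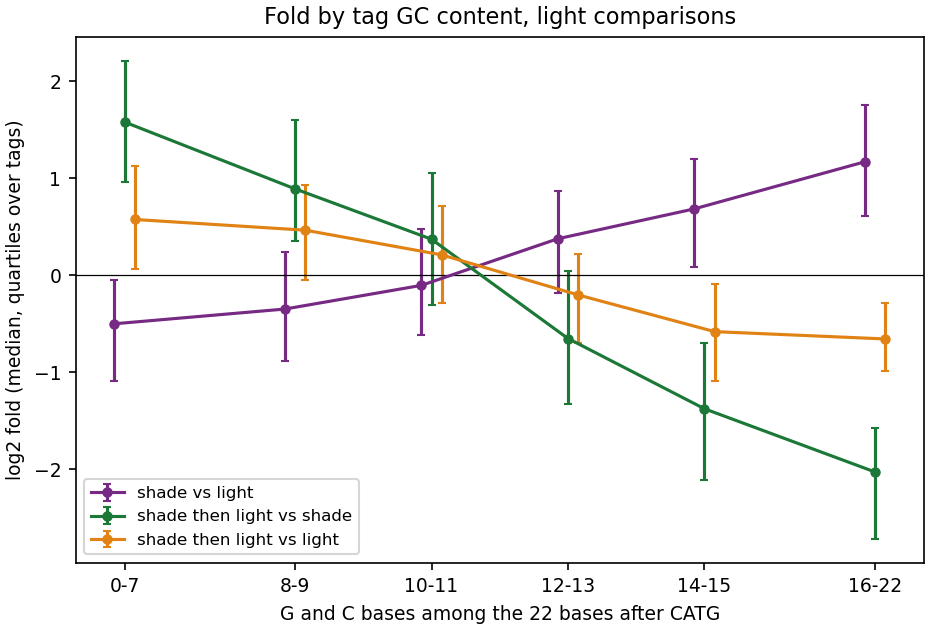
Median log2 fold, with quartiles, of tags grouped by the number of G and C bases among the 22 bases after CATG, in the 3 light comparisons. The fold of shade then light over shade falls from 1.58 in the GC-poorest group to -2.03 in the GC-richest.

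Most tags that differed in shade lay on the light side of the shade library when light returned. Without centring, 449 of the 459 shade calls (97.8%) did so, 197 of the 204 lower tags and 252 of the 255 higher tags. Of the 177 tags called lower in shade among the 2712 tested in both pairs, 152 were called higher after light, and of 243 called higher 191 were called lower. After GC centring, 109 of 147 tags called lower in shade were called higher after light, with median log2 folds of -2.08 and 2.31, and 50 of 103 called higher were called lower, with medians of 1.87 and -1.86.

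CATGTTGGGTCTGGTTGCACTCGCCT rose 14.54-fold after light (11.5 to 18.6; 27.4-fold GC-centred), to 11405 ppm, and CATGTTCGGGTTCTTCGTTCAGGCCA rose 13.1-fold (10.7 to 16.1; GC-centred log2 fold 4.10), to 13912, above its level of 8504 in constant light. CATGGGTCTACGCCACCAAGTTTGTG rose 19.4-fold (12.2 to 32.5; 25.4-fold GC-centred), to 3798. CATGAGCTCAAAGTGGTGGCTTCTCC, chosen here after its values were seen, was listed under the 3 regimes only in shade, at 392 ppm. Both pairs share the shade library, and unchanged libraries that share it gave 77.1% on the light side in simulation (highest of 10 simulations 83.7%). The covariance of the 2 folds was -0.76 against -0.12 in simulation over 1930 tags. Dividing the shade counts into independent parts gave 96.5%, a division that removes shared counting error but not effects of preparing the single shade library, from which the return is not separated.

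**Figure D3:**
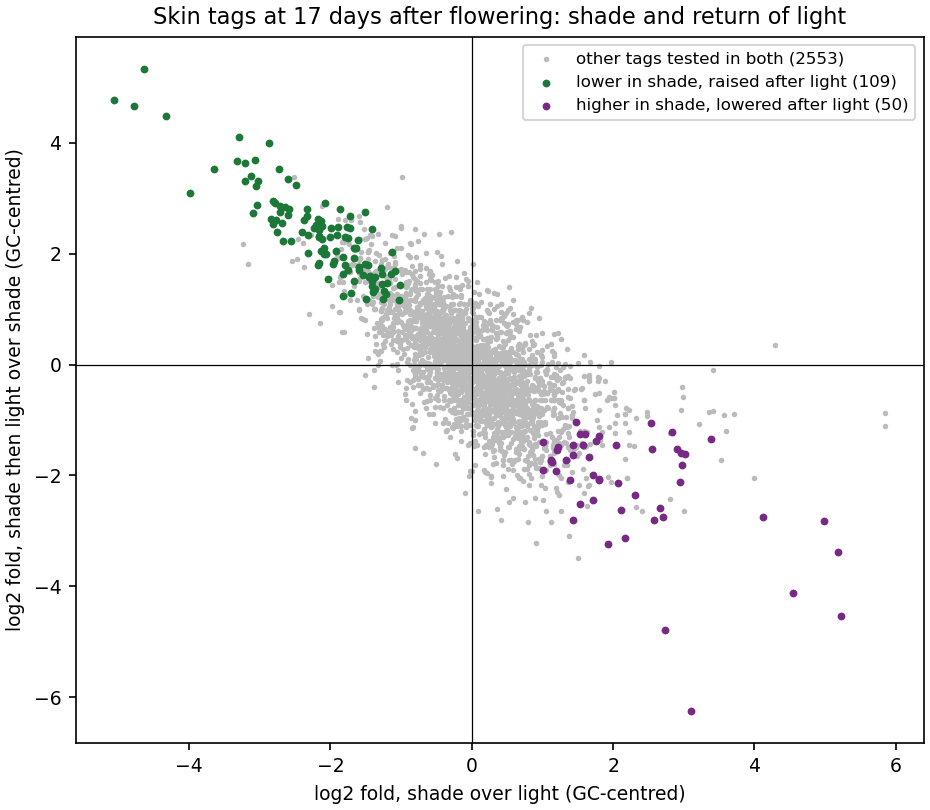
GC-centred log2 fold of shade over light (horizontal) and of shade then light over shade (vertical) for the 2712 skin tags tested in both pairs, each point a tag. The 109 green tags were called lower in shade and higher after light, and the 50 purple tags the other way; the 2 axes share the shade library.

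Set against berries that had never been shaded, skin 3 days after the return of light differed less. CATGATGGCTAAGATACTATAATGTG stood at 622 ppm after light and was unlisted in the other 8 libraries, at least 71.0-fold higher than in constant light. CATGTGGGGGGCGACAATGTGCTGGT, raised in shade, was still 19.7-fold higher (5.74 to 104) at 172 ppm. CATGTATGGACCACAGACTCCGCCGC was 7.81-fold lower (3.26 to 24.5), at 47.8 against 374 ppm. CATGGCCGAGGGAATGCTGGTTAGCC was 8.39-fold lower (2.21 to 71.0), at 19.1 against 161, but was not called with GC-centred folds.

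Fisher's exact test called 212 of 5054 tags, 120 higher and 92 lower, and the GC-centred test 96 tags, 46 higher and 50 lower. The exact test gave CATGATGGCTAAGATACTATAATGTG an adjusted p of 6.58e-39. With an assumed variation of 0.2 there were 20 calls and with 0.4 there were 2. The GC-centred fold of CATGATGGCTAAGATACTATAATGTG was 48.8 against the same floor. The division depended on library size: the sum of listed tags gave 155 higher and 65 lower tags, median-of-ratios factors 93 and 126, and TMM factors 33 and 413.

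Development of the skin was followed from 2 to 7 to 9 weeks. Between 2 and 7 weeks CATGGCTGGCTTTGTGCTGAAAGCCC fell from 18310 to 53.7 ppm, 341-fold (195 to 660), and CATGCCTAGTGGTTCGAGTGGGAGCG fell from 4611 to 8.96, 515-fold (142 to 4254). CATGTCTCGAAGGCCTGGTCTGTGTC rose from 184 to 13655 ppm, 74.3-fold (57.9 to 96.9), and became the second commonest tag of the library. CATGACTTTGTCACGTGGATGAGAAA rose 72.5-fold (27.9 to 269), from 11.7 to 846. CATGTGCCAACCTACGCAGCTACCCT, the leading tag at 2 weeks, was 58.5-fold lower at 7 weeks, at 851 ppm.

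In that pair 1728 of 5823 tags were called by Fisher's exact test, 625 higher and 1103 lower, with an adjusted p of 4.22e-68 for CATGACTTTGTCACGTGGATGAGAAA in the exact test. Median-of-ratios factors moved the division to 813 higher and 845 lower. Sequences with undetermined bases held 9.19% of the 7-week library and 0.025% of the 2-week library, so stage and that difference in reading quality coincide here.

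Between 7 and 9 weeks the skin turned over again. CATGTATGCACCTTTCCAATTATCTT was unlisted at 7 weeks and reached 3414 ppm, at least 254-fold higher, and CATGTCAAGTGCTTGCGTGTTGTTTA rose from 31.4 to 7667, 245-fold (118 to 609). CATGGCACCTGCAAGTCCCTTCTCTT fell from 1648 ppm to unlisted, at least 137-fold lower. CATGGGTCTACGCCACCAAGTTTGTG, one of the tags lowered by shade, fell from 967 to 12.04 ppm, 80.4-fold (27.1 to 393). Fisher's exact test called 1231 of 4756 tags, 568 higher and 663 lower, with an adjusted p of 1.17e-63 for the last tag in the exact test.

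Seen over the 3 stages, 893 skin tags fell and 318 rose by 7 weeks with no second call. In the second step 398 rose and 316 fell with no first call. Another 287 rose and then fell, 150 fell and then rose, 60 fell in both steps and 20 rose in both. CATGTGTGATCAGTGGTTGCCACTAG belonged to the last group, unlisted at 2 weeks, at 143 ppm at 7 weeks and at 17208 at 9 weeks. CATGTGCCAACCTACGCAGCTACCCT fell and then rose 18.6-fold, to 15795. CATGGACGAGGATGGTCCTTCTGCTG went from 406 to 6315 and back to 538 ppm, and CATGTTCGGGTTCTTCGTTCAGGCCA went from 8504 to 2374 and then to 72.2. These 4 tags were chosen after their values were seen, as frequent members of their groups. Both steps share the 7-week library, so its counting error and preparation alone can give a rise and then a fall, or the reverse. How much they add to these groups was not tested.

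Seed was followed over the same stages, first between 2 and 7 weeks. CATGCAAGTTGTCTGGTTCTAGGGCT was unlisted at 2 weeks and reached 199727 ppm at 7 weeks, at least 5680-fold higher, and CATGATCTTACCACCGGCAGCTAAGA went from unlisted to 47107, at least 1340-fold higher. CATGAGAGGATGTCAACCATCATCCT fell from 2462 to 28.2 ppm, 87.2-fold (29.4 to 426), and CATGTTGGGTAGCGTGTAAACCTCTT fell 55.4-fold (14.9 to 465), from 1043 to 18.8. Of 2320 tags, 1087 were called by Fisher's exact test, 262 higher and 825 lower, with an adjusted p of 3.03e-27 for the last tag in the exact test.

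The median log2 fold of tags listed at both seed stages was -1.03. Relative to the median of tags of like GC content, 691 tags were called, 400 higher and 291 lower, and TMM factors gave 370 higher and 392 lower. The direction of all 4 leading seed tags was the same under each of these scalings. Their GC-centred folds were 11841 and 2793 against the same floor for the 2 higher tags, and 40 and 25.4 for CATGAGAGGATGTCAACCATCATCCT and CATGTTGGGTAGCGTGTAAACCTCTT.

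Between 7 and 9 weeks some of the commonest 7-week seed tags fell and others stayed high. CATGCAAGTTGTCTGGTTCTAGGGCT fell to 66.8 ppm, 2990.5-fold lower (1975 to 4773), and CATGATGTACAATGAGAGTTGAGGTT fell from 11920.2 to unlisted, at least 1309-fold lower. CATGGGACAGGTGGCACCTAGAGGTG went from unlisted to 5243 ppm, at least 186-fold higher, and CATGGAACGGCCGACACCCCATAACT rose from 18.8 to 3309, 176-fold (48.6 to 1454). CATGGTAGGCTGTACTTTCAAGCTTC rose 109-fold (80.8 to 152), from 395 to 43191 ppm. CATGAGTGGGTTGGGTTTCCATCCTT, chosen after its values were seen, stood at 30163 ppm at 7 weeks and 40780 at 9 weeks, after 46.9 at 2 weeks.

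In that pair 1107 of 4060 tags were called by Fisher's exact test, 766 higher and 341 lower at 9 weeks, with an adjusted p of 1.54e-126 for CATGGAACGGCCGACACCCCATAACT in the exact test. With GC-centred folds 889 were called, 468 higher and 421 lower, and CATGGGACAGGTGGCACCTAGAGGTG was 95.9-fold higher against the same floor and CATGGAACGGCCGACACCCCATAACT 109-fold higher. Over the 3 stages, 149 seed tags rose and then fell, 51 rose in both steps, 96 fell and then rose and 52 fell in both. The largest groups were 677 that fell with no second call and 619 that rose with no first call. These groups rest on calls without centring. Median log2 folds of tags listed at both stages were -1.03 in the first step and 0.37 in the second. Scaling of the shared 7-week library alone can therefore give a fall and then a rise, and its share in these groups was not tested.

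Young skin and young seed were each set against flowers, a different tissue as well as an earlier stage. In skin at 2 weeks CATGCGTCTGTACTTTGACTTTGGAT stood at 1118 ppm against 10.8 in flowers, 103-fold higher (35.0 to 503), and CATGGGCATTAAGCAGTGCCCACTGA at 2101 against 21.7, 97.0-fold higher (44.3 to 265). CATGTCCACCCTCTTGGGAGGGCAAG was 65.6-fold lower in skin (22.04 to 321), at 8.76 against 574 ppm, and unlisted in seed. CATGTCATTTGGTCTTGGACTTATAA was 43.9-fold lower in skin (11.7 to 370), at 5.84 against 256. Fisher's exact test called 1424 of 6527 tags, 859 higher and 565 lower in skin, with an adjusted p of 6.16e-21 for the last tag in the exact test; 8.46% of the flower library consisted of sequences with undetermined bases, against 0.025% of the skin library.

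In seed at 2 weeks CATGGCCACACAGGAGGCATCTAGGG was 53.6-fold higher than in flowers (19.96 to 202), at 774 against 14.4 ppm, and CATGAAGAAGGTGGCCTATGTCGCGG, unlisted in flowers, was at least 41.1-fold higher at 445. CATGTGTGAAACTTGCAGATGTCAAC was 21.1-fold lower (10.6 to 49.0), at 93.8 against 1975, and CATGGGAGCAACCTCCTACGCCGCCT 21.9-fold lower (5.94 to 182), at 23.4 against 513. Fisher's exact test called 615 of 4527 tags, 384 higher and 231 lower, with an adjusted p of 1.82e-12 for the last tag in the exact test. The GC-centred fold of CATGAAGAAGGTGGCCTATGTCGCGG was 32.6 against the same floor. This balance depended on scaling, with 189 higher and 339 lower tags after GC centring, 103 and 850 under TMM factors, and 207 and 345 under median-of-ratios factors.

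**Figure D4:**
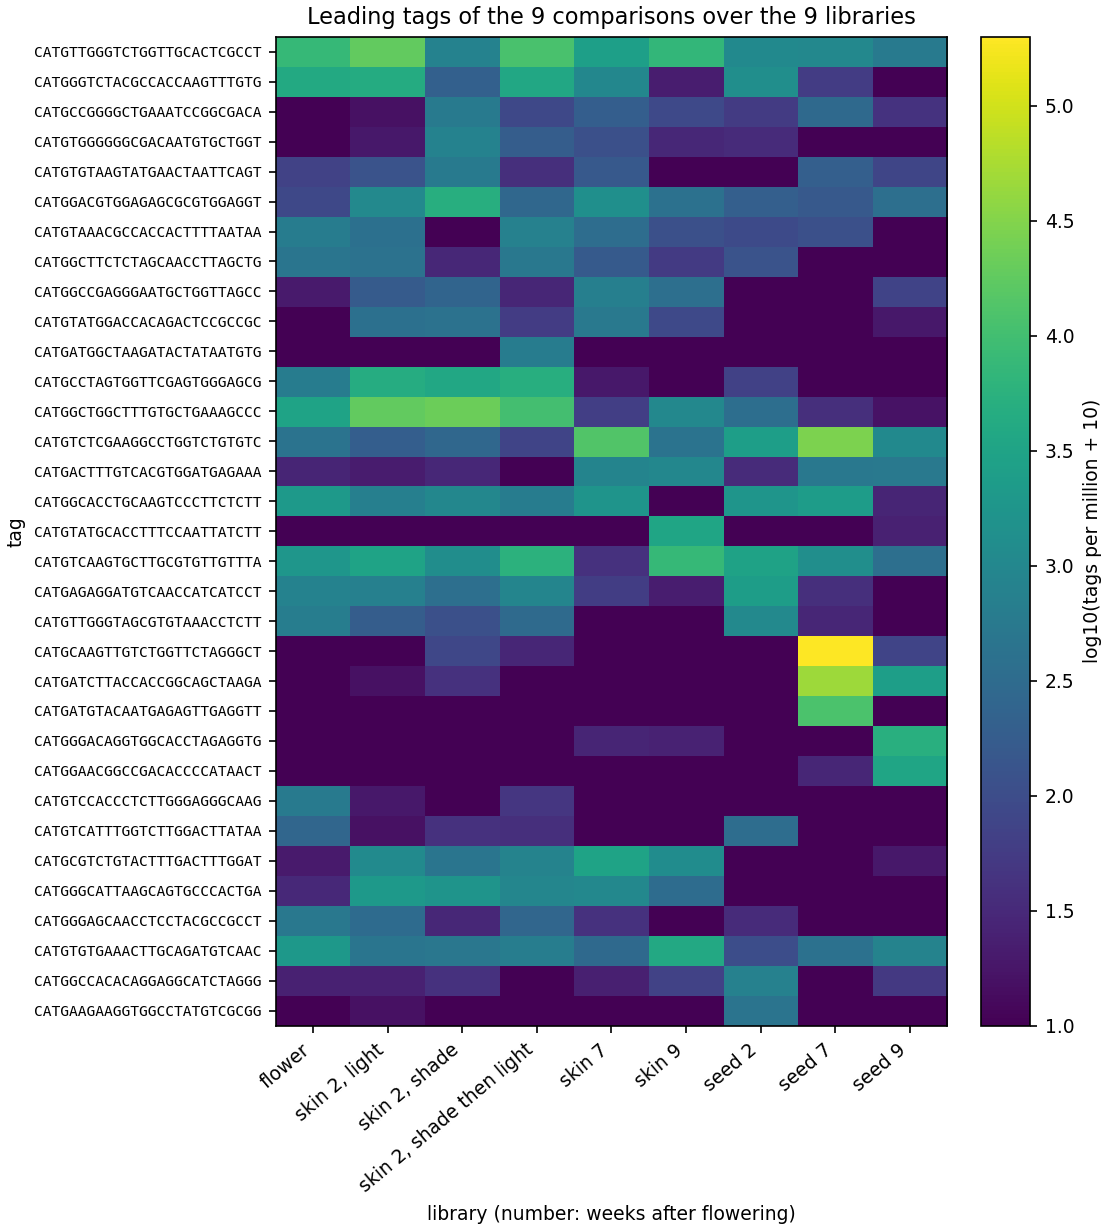
Value in ppm, as log10 after adding 10, of the 2 leading tags per direction of each of the 9 pairs of libraries (rows) in the 9 libraries (columns, numbers are weeks after flowering). CATGCAAGTTGTCTGGTTCTAGGGCT reaches 199727 ppm in seed at 7 weeks, the highest value drawn.

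Skin and seed were also compared over the 3 stages together. The tag CATGCGTCTGTACTTTGACTTTGGAT was higher in skin at every stage, with 1118, 3108 and 1228 ppm at 2, 7 and 9 weeks against unlisted, unlisted and 9 in seed, a log2 difference of 6.18 ± 0.59 (SE, 3 stages; adjusted p 0.0446, limma). In all 48 tags lay at least 4-fold higher in each of the 3 light-exposed skin libraries than in any seed library, and 5 tags the other way, a count made without a test and after the values were seen, with values under 20 ppm taken as 20. With unlisted values at the floor of 3 tags, 35 of the 48 and all 5 stayed at least 4-fold apart. CATGGGCATTAAGCAGTGCCCACTGA, one of the 48, had at least 321 ppm in those skin libraries and was unlisted in seed. CATGGGCTGTGTTTTGCGCACCTCCC, one of the 5, had at least 179 ppm in seed and at most 8 in those skin libraries.

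Of 2355 tags tested with limma, 1 was called, higher in skin, while 488 had an unadjusted p under 0.05. Without the 2-week pair or the 7-week pair 0 tags were called, and without the 9-week pair 155. The call was also lost with TMM factors and with a pseudocount of 5, which gave 0 calls each. Other settings raised the count, to 688 without a filter, 59 with undetermined bases assigned and 40 with a pseudocount of 50.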

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

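The tests of the positions of undetermined bases and of a constant share of late-seed tags (a chi-square, then a simulation picked once the chi-square result was known), the setting with undetermined bases assigned and the one without carry-over were chosen after the result was seen.

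Sequences with undetermined bases, which the comparisons did not use, held 8.46% of the flower library, 9.19% of skin at 7 weeks and 9.81% of skin at 9 weeks, and under 0.05% of each of the other 6 libraries. Their positions followed nearly the same profile in the 3 libraries, with a lowest correlation over the 26 positions of 0.9992, which is consistent with a step shared by these libraries, such as a sequencing run. At least 99.3% of these counts matched a complete tag of the same library. Those with a unique match (65.9% of these counts in flowers, 67.4% in skin at 7 weeks and 61.0% at 9 weeks) were then given to that tag. Skin calls moved from 1728 to 1789 (7 against 2 weeks) and from 1231 to 1362 (9 against 7 weeks). For 7 against 2 weeks the division moved from 625 higher and 1103 lower to 753 and 1036. For skin against flower it moved from 859 and 565 to 812 and 697, and for seed against flower from 384 and 231 to 326 and 273. The main tests left these counts out but kept them in the library size, which lowers the values of the 3 libraries. No biological explanation was tested, and a shared run stays confounded with stage for the skin pair of 2 and 7 weeks and for both flower pairs.

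Log2 folds followed the GC content of tags in the 3 light comparisons. The trend was steepest for shade then light against shade, at -0.39 per G or C base. Outside the light comparisons, seed at 9 against 7 weeks had a slope of 0.151, beside -0.151 for shade then light against light. The tests that follow cover the light comparisons only. Among 83 pairs of tags that differ by 1 base and by 1 G or C, the GC-richer tag stood 0.455 higher (log2; 95% bootstrap interval 0.263 to 0.647) in shade over shade then light, 117% of the slope across tags, which argues against a change of GC-rich transcripts as the whole cause, since 2 forms of a transcript would move together. The trend persisted over the 366 tags unlisted in both late seed libraries (rho -0.55 against -0.63 for all tags), which argues against late-seed tags as its source. GC-dependent recovery of tags may account for it in this pair of libraries. For shade against light it stays open, since the pair difference there was 0.020 (-0.16 to 0.20) against a slope of 0.18; for shade then light against light it was -0.43 (-0.58 to -0.29) against -0.15, and near copies can come from different genes.

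The shade library held 40 counts of 16 tags specific to seed at 9 weeks, 0.098% of their seed counts (0.070 to 0.133), and lit skin listed none of them. The indexes of the shade and the 9-week seed library differ at 1 base, so misread indexes could be the source, which needs 1 share for all 16 tags; a chi-square gave p = 0.0295 against that and the later simulation with single tags unlisted p = 0.195, neither an exact test, and with so few counts the source stays open. Skin at 7 and 9 weeks, with indexes 2 bases away, also listed 15 and 32 of these counts, and of 35236 counts of tags specific to seed at 7 weeks, whose index is 1 base away from 3 skin libraries, shade listed 12, shade then light 4 and skin at 7 weeks 0. The late-seed tags were chosen as unlisted in flowers and 2-week seed, so that choice itself left little room for young seed as their source. Separately, 14 other tags of 2-week seed stood at a ratio of 0.893 (0.557 to 1.38) in shade over light. That ratio gave no sign of more young seed tissue in the shaded skin, and it does not bear on the source of the late-seed tags. Leaving out all tags within the limit of such carry-over left 456 of the 459 calls.

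Between 2 and 7 weeks, 25 tags rose in skin and fell in seed and 8 fell in skin and rose in seed, fewer than the 71.4 and 18.7 of independent tissues, while 308 fell in both against 181.8. Between 7 and 9 weeks, 33 tags rose in skin and fell in seed and 63 fell in skin and rose in seed, against 23.1 and 53.2, while 111 rose in both against 70.9 and 51 fell in both against 17.4. GC-centred, the opposite moves were 11 and 24 in the first step, against 27.5 and 41.4, and 37 and 37 in the second, against 32.3 and 29.8, while 72 rose and 142 fell in both tissues in the first step, against 23.1 and 49.3. The imbalance between the 2 opposite moves did not hold with centring, and no difference between the tissues was tested. CATGTGCCAACCTACGCAGCTACCCT was one of the 33, going from 851 to 15795 ppm in skin and from 6369 to 2623 in seed. CATGCCTGGTGCGGGCTACGGTGGCT was one of the 63, going from 2109 to 189 in skin and from 1110 to 11372 in seed.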

How the results depend on the processing

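The GC-centred setting, the form of the test with assumed variation, pseudocounts, the treatment of undetermined and near-identical tags, unlisted tags given 1 count, the carry-over setting and TMM for skin against seed were chosen after the data had been seen; the others were planned. The leading tags made 180 entries of a tag in a pair, since some tags led in more than 1 pair. None of these entries changed direction in the settings compared tag by tag. Joining on the first 25 bases was not compared so, and the carry-over setting covered 20 of the entries. With GC centring 12 of the 180 were no longer called, and with an assumed variation of 0.2 also 12 and of 0.4 36. Without a count minimum 5 were lost, with TMM factors 3, and 1 each with median-of-ratios factors and the sum of listed tags.

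Counts are given in the order shade against light (459), shade then light against shade (739), shade then light against light (212), skin 7 against 2 weeks (1728), skin 9 against 7 (1231), seed 7 against 2 (1087), seed 9 against 7 (1107), skin against flower (1424) and seed against flower (615). An assumed variation of 0.4 left 25, 24, 2, 327, 297, 501, 323, 268 and 46, by construction of a wider null spread, and 0.2 left 189, 471, 20 and 294 in the 1st, 2nd, 3rd and last pair. GC centring gave 285, 318, 96 and, for seed 7 against 2, 691. TMM factors shifted libraries by between -0.64 (seed, 2 weeks) and 0.43 (seed, 9 weeks) on the log2 scale and gave 750 for shade against light (105 higher, 645 lower), 446 for shade then light against light (33 and 413) and 953 for seed against flower (103 and 850); the cause was not tested. Without a count minimum 139 were called in shade then light against light, among 17154 tags tested. All other counts stayed within 1.5 times.

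Skin against seed, with 1 call, gave 688 without a filter (30025 tags tested), 3 without the stage block, 0 with a pseudocount of 5, 40 with 50, 0 with TMM factors and 59 with undetermined bases assigned; leaving out a stage gave 0 to 155, and the cause was not tested. Of 10 divisions of the 6 libraries into 3 and 3 with the stage block, 1 gave as many calls, the real one, and the highest other gave 0. Most of these divisions put both libraries of a stage on the same side. With the block their contrast rests on 1 stage, so they could hardly give a call and are not comparable with the real division. Without the block the real division gave 3 calls and another division (skin at 2 and 7 weeks with seed at 2 weeks) gave 5. In either case 10 divisions are too few for a share under 0.05. Median-of-ratios factors gave 384 higher and 374 lower tags for seed at 7 against 2 weeks, against 262 and 825 with label totals. The share of shade calls on the light side (97.8%) was 90.1% with TMM factors, 100% for the 25 calls under variation 0.4 and 96.5% with divided shade counts. With GC centring it was 97.6%, counted only over the 250 calls tested in both pairs.

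Not run were the tests of edgeR and DESeq2, the settings that need transcript sequences and the medians of gene lists; single tags were the main feature. The pairs of libraries allowed no paired test, with 1 library per group; skin and seed were paired by stage. In the simulated seed and flower pair, the lowest of the 9 pairs, 46 of 63 tags changed 4-fold (73.0%) were recovered, with 4588 tags tested. The changed tags were drawn from those well above the count minimum, so recovery of rarer tags is not known.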

Other observations

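Some tags were found in 1 library only. Of tags with at least 100 ppm, 55 were listed in seed at 7 weeks alone and 41 in seed at 9 weeks alone. There were 6 in flowers, 4 in skin at 9 weeks, 4 in seed at 2 weeks, 1 in skin after shade then light, and 0 in the other 3 libraries. The counts were not screened for 1-mismatch neighbours of far more frequent tags. Seed held 379 such neighbours at 7 weeks and 1286 at 9 weeks, and lit skin at 2 weeks 1148. Skin at 2 weeks had 3 libraries, so its tags could be listed in more than 1 of them. CATGATGTACAATGAGAGTTGAGGTT was the most frequent of the 55, with 11920.2 ppm, and CATGCATGCATCCATAGGTCCCCGCC the most frequent of the 41, with 1727. CATGAGGCAGTTGGGGCTTTTGTAAC had 485 ppm in skin at 9 weeks, and CATGCCAAGAGGCTGGTGGGCAGATT 177 in flowers.

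A pair of near-identical tags was present in all 9 libraries at changing proportions. CATGTCTCGAAGGCCTGGTCTGTGTC had 13655 ppm in skin at 7 weeks, where CATGTCTCCAAGGCCTGGTCTGTGTC had 6534. In skin at 9 weeks the first had 421 and the second 1697, and in seed at 2 weeks they had 2555 and 5415. In seed at 7 weeks they had 28149 and 21357, so both tags peaked there.

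The tags raised by the return of light, 178 after GC centring, were followed in libraries that played no part in choosing them. The hypotheses that tags raised by re-exposure to light fall in skin between 7 and 9 weeks, and that they are lower in seed than in flower, were written before their results were seen; the other 4 pairs were computed beside them without a prediction. Their median log2 fold in skin at 9 against 7 weeks was -0.36 over 140 tags (29 called higher, 48 lower), at percentile 0.5 of 10000 random lists matched on expression and GC content. In seed at 2 weeks against flower it was -0.46 over 169 tags (19 higher, 52 lower), at percentile 0, below all random lists, whose central 95% ran from 0.045 to 0.37. The median also lay below all random lists in skin at 7 against 2 weeks (-1.57, with 114 tags called lower and 1 higher), in seed at 7 against 2 weeks (-1.83, with 75 lower and 1 higher) and in seed at 9 against 7 weeks (-0.06, with 30 lower and 11 higher). For skin at 2 weeks against flower it lay inside them (0.25, percentile 74.4, with 10 lower and 42 higher). Both medians lay where the hypotheses put them, though single tags went both ways, and there are no replicates or gene names. The random lists were matched on counts in the compared pair, not on abundance in young skin. The comparison therefore cannot separate a trait of light-raised tags from a trait of tags frequent in lit young skin.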
